A study of Saccharomyces cerevisiae with 10 samples.

How the data were processed

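The series holds RNA-seq of 10 libraries from BY4743 diploids grown to mid-log phase in rich medium, 2 replicates in each of 5 groups: naive, [ESI+], and deletions of HOS2, SET3 and SNT1. Per the labels' protocols, total RNA was taken with hot acid phenol and given ERCC spike-ins. Polyadenylated RNA was bound to beads and copied there by reverse transcriptase, the copies were sheared, libraries were made with a kit for DNA, and paired ends were read on an Illumina HiSeq. The labels do not state whether strand was kept, so it is not known whether reads from overlapping genes were told apart. The deposited values of each library are expected counts and TPM (transcripts-per-million), per the file headers, for 7218 targets, 92 of them ERCC RNAs. Per the submitters' processing notes they come from kallisto 0.44 and genome build R64. Expected counts are estimated reads or fragments per target without normalization, not whole where reads are shared between targets. TPM in the deposited tables is scaled over all targets, spike-ins and ribosomal RNA included, and target lengths are coding lengths. Of 6685 open reading frames 6006 were found by name in the R64 annotation, which gave positions and products, and the others are mostly dubious reading frames and kept their systematic names.

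Expected counts were rounded, spike-ins were set aside, and genes were kept by edgeR's filterByExpr over the 5 groups, which left 6390 genes, 1391 of them with shared reads. edgeR 4.0.16 in R 4.3.3 was used with TMM library sizes and a robust quasi-likelihood fit with 1 coefficient per group over all 10 libraries. Contrasts gave each group against naive, [ESI+] against each deletion, an F-test over the 3 deletions and the deletions pairwise, each two-sided with Benjamini-Hochberg adjustment at 0.05. A log2 fold change's SE was its size over the square root of its F statistic. CPM use TMM-scaled library sizes. For 31 gene lists, camera (limma 3.58.1) was run with a preset correlation of 0.01 and with an estimated one, and fry was run too, adjusted over 124 tests, 1 per list and comparison with naive. Fry asks whether a list's genes move, on balance, one way, and does not compare them with other genes. The subtelomeric list holds the 241 genes wholly within 20 kb of a chromosome end, 194 of them tested. A fold against a group with 0 counts was bounded by a floor of 3 counts over the group, and groups with 1 to 3 counts have a ratio with an exact binomial 95% interval. Correlations and overlaps of fold changes were set against 100 simulations of unchanged groups that share the naive libraries.

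The tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named the deleted genes, the other Set3 complex subunits and 5 auxotrophic markers. Of genes past the threshold with both libraries of 1 group beyond both of the other and at least 5 CPM in 1 of them, it named the 12 highest and 12 lowest fold changes per comparison with naive. It added up to 4 members of each called list and up to 5 subtelomeric genes by smallest p, the 8 genes with the smallest largest p in all 3 deletions, and the 5 smallest p per direction in direct tests (10 in the F-test). The text drops names only from the end of each ranking. The alternatives fixed with them were DESeq2 1.42.0, its size factors in edgeR (RLE), spike-in library sizes, limma-trend on log2(TPM + 1), no filter and a filter at a mean of 10 CPM. Others were fits of only the groups compared, a replicate block, a fold over 2, leaving out genes of shared reads, distances of 10 and 40 kb, and leaving out each library in turn. Fits without 1 library applied the filter anew, and it asks for fewer libraries where a group holds only 1.

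Other alternatives were chosen after seeing the data: subtraction of each library's reads at silent genes, removal of its trend with coding length, both together, and nuclear protein-coding genes alone. Silent genes are nuclear genes of at least 300 bases and a mean under 0.2 CPM per kb over the libraries of other groups, [ESI+] not counted among those others. The median count per kb over them, times target length, was subtracted, and mitochondrial targets were left out. The length trend was a loess of span 0.5 per library, used as an offset. A first definition counted [ESI+] among the others and left only 6 to 8 silent genes in the other groups, so it was replaced after its result was seen. Calls under the first and the present definition were 1556 against 1593 for [ESI+], 508 against 525 for hos2, 164 against 174 for set3 and 29 against 30 for snt1. The spread against which a correlation's shift was judged is the SD of its values without 1 library.

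The fit was tested on simulated data with changes of known size, for [ESI+], hos2, set3 and snt1 in this order. It called 53.7%, 25.4%, 52.2%, 38.8% of genes changed 2-fold, 94.0%, 97.0%, 89.6%, 92.5% of those changed 4-fold and 95.5%, 97.0%, 97.0%, 92.4% of those changed 8-fold, with 0.115% to 0.231% of unchanged genes and 0 of 30 unchanged lists called by camera. Genes were drawn independently there and lists at random. The simulation therefore cannot show how often camera calls unchanged lists whose genes are correlated. The sum of counts per library ran from 8327730 (set3 replicate 2) to 80651800 (set3 replicate 1), and TMM factors from 0.629 to 1.58. With 2 replicates per group, splits of the samples were not counted. All 10 libraries and their target tables in this RNA-seq series were used.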

Results

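Messenger RNA was sequenced from diploid budding yeast of strain BY4743 in mid-logarithmic growth in rich glucose medium. The 10 libraries form 5 groups of 2 replicates. They are naive diploids, diploids in the [ESI+] state, and diploids lacking HOS2, SET3 or SNT1. [ESI+], for expressed sub-telomeric information, is a heritable, prion-like state studied for the expression of genes near chromosome ends. Hos2 is a histone deacetylase, Set3 binds methylated histone H3 and Snt1 is a SANT-domain protein, and all 3 are subunits of the Set3 histone deacetylase complex. The series sets the transcript profile of [ESI+] beside those of cells without this complex's function. The study's binding and histone acetylation profiles are not part of this RNA-seq series.

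The sum of estimated counts, the depth, was 27318400 and 18274400 in naive replicates 1 and 2 and 55180700 and 58713200 in [ESI+] replicates 1 and 2. It was 65121800 and 19461600 in the hos2 deletion, 80651800 and 8327730 in the set3 deletion, and 22057000 and 24831600 in the snt1 deletion. The ERCC spike-in RNAs took between 0.946% ([ESI+] replicate 1) and 5.19% ([ESI+] replicate 2) of a library. Ribosomal RNA took between 8.62% ([ESI+] replicate 2) and 28.0% ([ESI+] replicate 1). In the [ESI+] libraries, nuclear genes silent elsewhere had a median of 0.347 and 1.55 counts-per-million (CPM) per kb, against 0 to 0.110 in the other 8 libraries. Mitochondrial targets had a median of 3.50 and 13.4 CPM per kb in [ESI+], against 0.0251 to 0.239 elsewhere. Fold changes are log2 with their standard error (SE), from 2 libraries against 2, and adjusted p-values for genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The labels do not say whether the replicates came from separate cultures, so these p-values measure only the spread between these libraries.

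**Figure D1:**
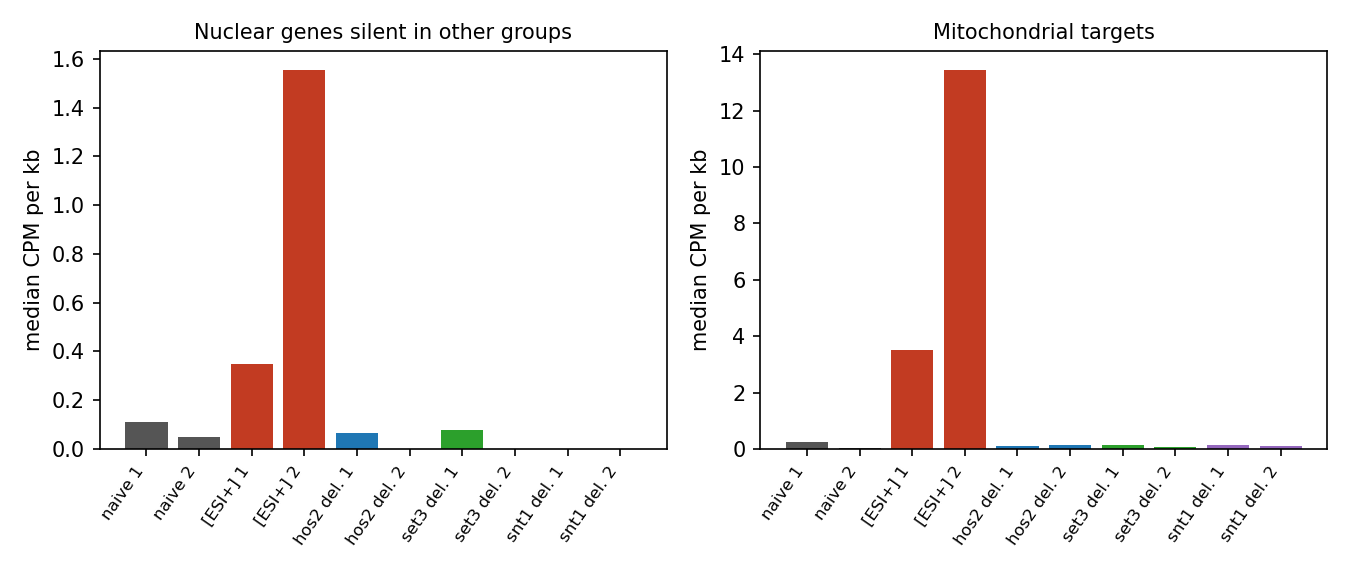
Median CPM per kb in each library over nuclear genes silent in other groups (left) and over mitochondrial targets (right), 1 bar per library. The tallest bars are those of [ESI+] replicate 2, at 1.55 and 13.4 CPM per kb.

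Each deleted gene was nearly absent from the libraries labelled as lacking it. HOS2 (YGL194C, chromosome VII, 140368 to 141726, build R64) had 3 and 0 counts in the 2 hos2 deletion libraries against 164 and 68 in naive replicates 1 and 2, or 0.541% of the naive level (95% interval 0.111 to 1.60%). SET3 (YKR029C, chromosome XI, 497578 to 499833) had 2 and 0 counts in the 2 set3 deletion libraries against 163 and 51 in naive replicates 1 and 2, or 0.480% of the naive level (95% interval 0.0577 to 1.75%). SNT1 (YCR033W, chromosome III, 186489 to 190169) had 1 and 4 counts in the 2 snt1 deletion libraries against 986 and 504 in naive replicates 1 and 2, or 0.419% of the naive level (95% interval 0.136 to 0.979%). These intervals are exact binomial ones and cover counting error only, as PCR copies are not independent molecules. In every other library HOS2 stayed between 4.20 and 13.4 CPM, SET3 between 3.97 and 9.97 CPM and SNT1 between 34.4 and 73.4 CPM. The fitted log2 fold changes against naive were -7.40 ± 0.54, adjusted p = 7.54e-05 for HOS2, -7.47 ± 0.55, adjusted p = 7.71e-05 for SET3 and -7.90 ± 0.51, adjusted p = 3.59e-05 for SNT1. HOS4 and SIF2, the other core subunits tested, had log2 fold changes between -0.22 and 0.076 in the 3 deletions, none past the threshold.

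**Figure D2:**
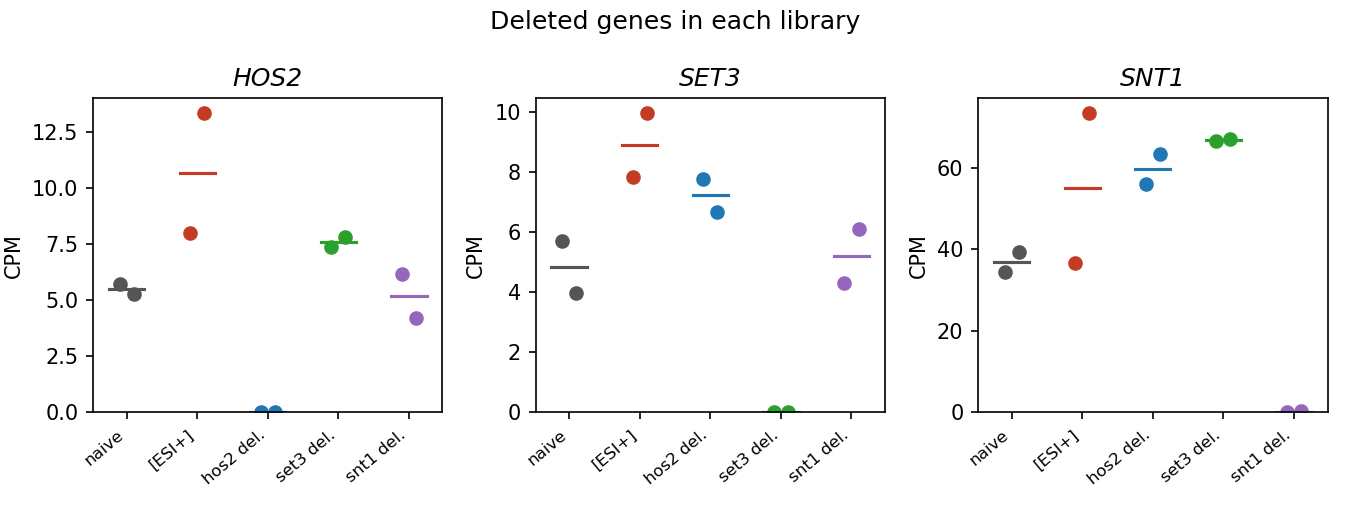
CPM of HOS2, SET3 and SNT1 (y axis, linear) in each library by group, with a line at each group's mean. Each gene lies near 0 only in the 2 libraries of its own deletion.

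The comparison of [ESI+] with naive diploids asks which transcripts differ in the heritable state. Transcripts of cell wall, respiratory, glycolytic and ribosomal protein genes were lower in [ESI+] and ribosome biogenesis transcripts higher, relative to other genes. These are list calls at camera's preset correlation, and each was lost with an estimated one (adjusted p = 0.527 to 0.687). CWP2, a covalently linked mannoprotein of the cell wall, fell by 2.29 ± 0.30 (log2, adjusted p = 0.000780; chromosome XI, 259253 to 259531), and CCW12, another, fell by 2.04 ± 0.34 (adjusted p = 0.00205). CYC1, cytochrome c, fell by 1.42 ± 0.20 (adjusted p = 0.00109), while UTP20, a factor of small-subunit assembly, rose by 1.42 ± 0.21 (adjusted p = 0.00134). Of 6390 genes tested, 1810 passed the threshold, 886 higher and 924 lower in [ESI+]. That count fell in every fit that left out 1 library, most without [ESI+] replicate 2 and least without naive replicate 1. Such fits also lose replication, so a fall need not come from the library left out alone. With spike-in library sizes the median of all genes was 0.80, and 32 genes passed. These rest on spike-in shares that differed within groups (0.946% and 5.19% in [ESI+]). The lists named above lay -0.75 (cell wall), -0.60 (respiratory), -0.94 (glycolytic), -0.60 (ribosomal protein) and 0.41 (ribosome biogenesis) from that median. After each library's reads at silent genes were subtracted per kb, a correction chosen after seeing the data, 641 of the 886 genes called higher and 774 of the 924 called lower still passed in the same direction. With the trend on coding length removed, also chosen after seeing the data, 409 and 678 did, and with both corrections 359 and 568.

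Highest over naive were transposon, mitochondrial and duplicated-gene targets. YHR054C (1792 counts in the 2 [ESI+] libraries against 0) was at least 160.1-fold higher and the Ty element YPL257W-B at least 119-fold higher, against a floor of 3 counts over the naive group. Both share reads with near-identical sequences, so their counts are uncertain. Of the mitochondrial genome, Q0255 was 474-fold (95% interval 85.0 to 18738) and BI3 192-fold (95% interval 53.0 to 1585) higher by ratio to 1 and 2 naive counts. Both intervals are exact binomial ones that cover counting error only, as PCR copies are not independent molecules. The intron reading frame BI4, which shares reads with COB, was higher by 7.29 ± 1.14, adjusted p = 0.00318 and ATP6 by 6.22 ± 1.01, adjusted p = 0.00247. The Ty element YOL103W-B, with shared reads, was higher by 7.29 ± 2.01, adjusted p = 0.0448 and COX3 by 5.99 ± 1.33, adjusted p = 0.0145, but these calls held in only 0 and 1 of the 4 fits that left out 1 library. Mitochondrial reads in [ESI+] went with the reads at silent nuclear genes given above. Lowest were targets that share reads with others. YCR087C-A was at least 951-fold lower, YHR137C-A at least 663-fold, YJL026C-A at least 618-fold and CPP2 at least 502-fold lower. CUP1-1 and CUP1-2, identical copies of the metallothionein gene whose reads cannot be told apart, both had -4.49 ± 0.90, adjusted p = 0.0155, a call lost in 2 of the 4 fits without 1 library.

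Several fixed gene groups were lower in [ESI+]. Of the 137 ribosomal protein genes tested, 0 rose and 45 fell (0 and 54 adjusted over the list alone). For ribosomal proteins the mean log2 fold change was -0.68, camera adjusted p = 5.62e-11, and adjusted p = 0.687 with an estimated correlation, and both corrections together ended the call (-0.20, adjusted p = 0.174). RPL43A fell by 2.29 ± 0.29 (adjusted p = 0.000724; 114 of the list share reads with a paralog, RPL43A among them). Of the 18 glycolytic and fermentation genes tested, 0 rose and 10 fell (0 and 12 adjusted over the list alone). For glycolysis the mean log2 fold change was -0.98, camera adjusted p = 1.46e-05, and adjusted p = 0.687 with an estimated correlation. CDC19, pyruvate kinase, fell by 1.51 ± 0.35 (adjusted p = 0.00970), and TDH1, which shares reads with its paralogs, fell by 1.37 ± 0.30 (adjusted p = 0.00761). Of the 41 TCA cycle and respiratory chain genes tested, 0 rose and 16 fell (0 and 18 adjusted over the list alone). For this list the mean log2 fold change was -0.63, camera adjusted p = 1.00e-05, and adjusted p = 0.591 with an estimated correlation. COX5A, a subunit of cytochrome c oxidase, fell by 1.21 ± 0.20 (adjusted p = 0.00207). Of the 24 cell wall genes tested, 2 rose and 11 fell (2 and 14 adjusted over the list alone). For cell wall genes the mean log2 fold change was -0.75, camera adjusted p = 4.76e-05, and adjusted p = 0.527 with an estimated correlation. SPI1, a wall protein of late growth, fell by 1.73 ± 0.24 (adjusted p = 0.00115).

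General stress genes and histones were lower by smaller amounts, and with spike-in library sizes lay -0.44 and -0.45 from the median of all genes. Of the 31 general stress genes tested, 1 rose and 9 fell (1 and 11 adjusted over the list alone). For general stress the mean log2 fold change was -0.56, camera adjusted p = 0.0135, and adjusted p = 0.827 with an estimated correlation, and background subtraction ended the call (-0.47, adjusted p = 0.0724). HOR7 fell by 1.24 ± 0.25 (adjusted p = 0.00547) and SOD2, mitochondrial superoxide dismutase, fell by 1.65 ± 0.35 (adjusted p = 0.00709). Of the 10 histone genes tested, 0 rose and 2 fell (0 and 1 adjusted over the list alone). For histones the mean log2 fold change was -0.59, camera adjusted p = 0.0347, and adjusted p = 0.811 with an estimated correlation. That call was lost without [ESI+] replicate 2 (-0.43, adjusted p = 0.136), without naive replicate 1 (-0.59, adjusted p = 0.0723) and with background subtraction (-0.44, adjusted p = 0.144). It was also lost with the length trend removed (-0.31, adjusted p = 0.278) and with both (-0.080, adjusted p = 0.954). Linker histone gene HHO1 fell by 1.40 ± 0.29 (adjusted p = 0.00659). HTB1 had -0.72 ± 0.25, adjusted p = 0.0484, a call that every fit without 1 library lost, and its log2 fold change was 0.076 with spike-in library sizes, below the median of all genes there.

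Other groups were higher in [ESI+]. Of the 34 ribosome biogenesis genes tested, 14 rose and 1 fell (17 and 1 adjusted over the list alone). For ribosome biogenesis the mean log2 fold change was 0.46, camera adjusted p = 0.00101, and adjusted p = 0.661 with an estimated correlation. UTP22 rose by 1.18 ± 0.18, adjusted p = 0.00156 and NOP7 by 1.22 ± 0.22, adjusted p = 0.00339. Of the 19 early meiotic genes tested, 9 rose and 0 fell (9 and 0 adjusted over the list alone). For early meiotic genes the mean log2 fold change was 1.41, camera adjusted p = 0.00140, and adjusted p = 0.759 with an estimated correlation. ZIP1, of the synaptonemal complex, rose by 1.95 ± 0.44, adjusted p = 0.00872 and SPO22 by 1.28 ± 0.32, adjusted p = 0.0138. Of the 22 middle and late meiotic genes tested, 5 rose and 0 fell (5 and 0 adjusted over the list alone). For these later meiotic genes the mean log2 fold change was 1.33, camera adjusted p = 0.0109, and adjusted p = 0.811 with an estimated correlation. SPO75 rose by 1.30 ± 0.29, adjusted p = 0.00856 and the septin gene SPR3 by 3.27 ± 0.92, adjusted p = 0.0220. The SPR3 call held in only 1 of the 4 fits without 1 library. Both meiotic lists are of genes with few reads in naive cells, and both calls ended with background subtraction, at 0.38 (adjusted p = 0.291) and -0.26 (adjusted p = 0.837). The later one was also lost without [ESI+] replicate 2 (0.54, adjusted p = 0.177).

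Of the 26 genes of silencing and telomere proteins tested, 7 rose and 0 fell (10 and 0 adjusted over the list alone). For silencing the mean log2 fold change was 0.53, camera adjusted p = 0.00967, and adjusted p = 0.661 with an estimated correlation. SIR3, a structural protein of silent chromatin, rose by 1.14 ± 0.24, adjusted p = 0.00642, and YKU70, of the telomere-binding Ku complex, rose by 1.65 ± 0.36, adjusted p = 0.00772, calls that each held in only 2 of the 4 fits without 1 library. The list's call was lost without [ESI+] replicate 2 (0.37, adjusted p = 0.0523), once the trend of fold changes with coding length was removed (0.30, adjusted p = 0.0994) and with both corrections (0.19, adjusted p = 0.264). Genes wholly within 20 kb of a chromosome end were not called as a list. Of the 194 subtelomeric genes tested, 17 rose and 16 fell (12 and 8 adjusted over the list alone). For subtelomeric genes the mean log2 fold change was 0.28 (camera adjusted p = 0.493, and adjusted p = 0.912 with an estimated correlation). It was -0.12 without [ESI+] replicate 2 and -0.28 with background subtraction. It was 1.07 without [ESI+] replicate 1, 1.09 without naive replicate 1 and 0.94 without naive replicate 2. Fits without 1 library filter genes anew, so their members can differ from the 194 and these shifts are not those of 1 library alone. With no filter and all libraries in, the mean was 0.85 (camera adjusted p = 0.274). COX14, of cytochrome oxidase assembly, 14.8 kb from an end of chromosome XIII, fell by 1.66 ± 0.25 (adjusted p = 0.00134). IRC24 fell by 2.03 ± 0.32 (adjusted p = 0.00190) and YPR202W rose by 3.69 ± 0.64, adjusted p = 0.00251, both with shared reads.

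Of the 31 lists, 10 passed in [ESI+] against naive and the other 21 had adjusted p-values from 0.102 to 0.905. With an estimated correlation 0 passed (lowest adjusted p = 0.527, 0 with an unadjusted p under 0.05), and 4 passed by fry. Of 72 named calls against naive, 24 held in each of the 4 fits that left out 1 library, among them those of CWP2, CCW12, SPI1, CYC1, RPL43A, UTP20, UTP22, COX14 and IRC24. Those of CDC19, TDH1, SOD2, HHO1, ZIP1, SPO22 and SPO75 held in 2 of the 4. Leaving out [ESI+] replicate 2 ended 46 of them, naive replicate 2 ended 35, and [ESI+] replicate 1 and naive replicate 1 ended 13 each.

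The hos2 deletion was compared with naive diploids to find the transcripts that depend on the deacetylase subunit. The lists of hexose transporters and of general stress genes were lower and that of ribosome biogenesis higher at camera's preset correlation. Each call was lost with an estimated one (adjusted p = 0.122 to 0.329). HXT6 and HXT7, high-affinity hexose transporters with nearly identical sequence, fell by 4.49 ± 0.50 (adjusted p = 0.00184) and 3.85 ± 0.36 (adjusted p = 0.000192). BNA2, which starts NAD synthesis from tryptophan, fell by 3.62 ± 0.43 (adjusted p = 0.000940; chromosome X, 578860 to 580221). HXT4 fell by 3.59 ± 0.33 (adjusted p = 0.000179), the uncharacterised YKR075C fell by 3.46 ± 0.31 (adjusted p = 0.000179; chromosome XI, 579827 to 580750) and glycogen phosphorylase GPH1 fell by 2.75 ± 0.30 (adjusted p = 0.000578). Of 6390 genes tested, 489 passed, 189 higher and 300 lower. The count fell in every fit that left out 1 library, most without hos2 replicate 1 and least without naive replicate 1. Such fits also lose replication. With spike-in library sizes, which put the median of all genes at 0.25, 5 genes passed.

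Among the other most reduced transcripts, YFR052C-A (-3.27 ± 0.31, adjusted p = 0.000197) lies in a region of shared reads, and TMA10 had -2.93 ± 0.47, adjusted p = 0.00915, and the transcription factor gene ZNF1 -2.83 ± 0.31, adjusted p = 0.000593. Highest were FRE1, a plasma membrane ferric reductase (2.75 ± 0.49, adjusted p = 0.0143), the small nucleolar RNA snR44 (2.10 ± 0.51, adjusted p = 0.0390) and SIT1, a siderophore transporter (2.09 ± 0.28, adjusted p = 0.00211). YGR160W, an overlapping reading frame with shared reads, had 2.01 ± 0.38, adjusted p = 0.0145, HLR1 1.71 ± 0.34, adjusted p = 0.0134, the cyclin gene PCL1 1.64 ± 0.35, adjusted p = 0.0211 and UTP20 1.61 ± 0.21, adjusted p = 0.00184. The labels do not state whether strand was kept, so it is not known whether reads of snR44 and YGR160W were kept apart from those of genes they overlap.

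Of the 15 hexose transporter genes tested, 0 rose and 6 fell (0 and 8 adjusted over the list alone). For hexose transporters the mean log2 fold change was -1.496, camera adjusted p = 9.95e-11, and adjusted p = 0.122 with an estimated correlation. Of the 31 general stress genes tested, 0 rose and 16 fell (0 and 23 adjusted over the list alone). For general stress the mean log2 fold change was -1.28, camera adjusted p = 9.20e-19, and adjusted p = 0.329 with an estimated correlation. GLC3, the glycogen branching enzyme, fell by 2.03 ± 0.28 (adjusted p = 0.00211) and HOR7, a stress-induced gene, fell by 1.69 ± 0.25 (adjusted p = 0.00406). Of the 34 ribosome biogenesis genes tested, 21 rose and 0 fell (29 and 0 adjusted over the list alone). For ribosome biogenesis the mean log2 fold change was 0.89, camera adjusted p = 3.98e-20, and adjusted p = 0.207 with an estimated correlation. NOP7 rose by 1.44 ± 0.22, adjusted p = 0.00483, RPA190, the largest subunit of RNA polymerase I, by 1.26 ± 0.21, adjusted p = 0.00682 and UTP22 by 1.22 ± 0.18, adjusted p = 0.00406. Of the 41 TCA cycle and respiratory chain genes tested, 0 rose and 7 fell (0 and 11 adjusted over the list alone). For this list the mean log2 fold change was -0.57, camera adjusted p = 9.74e-08, and adjusted p = 0.527 with an estimated correlation. LSC2, of succinyl-CoA ligase, fell by 1.39 ± 0.22 (adjusted p = 0.00574). Of the 18 glycolytic and fermentation genes tested, 0 rose and 3 fell (0 and 5 adjusted over the list alone). For glycolysis the mean log2 fold change was -0.83, camera adjusted p = 4.06e-06, and adjusted p = 0.661 with an estimated correlation. Of the 21 iron regulon genes tested, 4 rose and 0 fell (4 and 0 adjusted over the list alone). For the iron regulon the mean log2 fold change was 0.53, camera adjusted p = 0.00640, and adjusted p = 0.527 with an estimated correlation. Its call was lost without naive replicate 1 (0.45, adjusted p = 0.104).

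Of the 194 subtelomeric genes tested, 3 rose and 11 fell (3 and 14 adjusted over the list alone). For subtelomeric genes the mean log2 fold change was -0.48, camera adjusted p = 0.000215, and adjusted p = 0.661 with an estimated correlation. With genes at 0 counts set to their bound the list's median was -0.40. IMD2, inosine monophosphate dehydrogenase, 8.25 kb from an end of chromosome VIII, fell by 2.33 ± 0.21 (adjusted p = 0.000179). MAL31, a maltose permease, fell by 1.60 ± 0.26 (adjusted p = 0.00574), and hexokinase gene HXK1 fell by 2.70 ± 0.42 (adjusted p = 0.00589). HXT1, HXT4, HXK1, IMD2, TIR1, BNA5 and NOP56 share some reads with related genes or overlapping reading frames in all comparisons, which makes their counts less certain. Without the 117 list members that share reads the mean was -0.25 and no longer passed (adjusted p = 0.142). Lower lists of smaller size were the DAN and TIR mannoproteins (0 rose and 2 fell of 8, 0 and 4 adjusted over the list alone; mean log2 fold change -0.84, camera adjusted p = 0.00102, and adjusted p = 0.329 with an estimated correlation), maltose genes (0 rose and 4 fell of 13, 0 and 4 adjusted over the list alone; mean log2 fold change -0.84, camera adjusted p = 0.000601, and adjusted p = 0.463 with an estimated correlation) and galactose genes (0 rose and 2 fell of 9, 0 and 3 adjusted over the list alone; mean log2 fold change -0.70, camera adjusted p = 0.0108, and adjusted p = 0.527 with an estimated correlation). So were thiamine genes (0 rose and 0 fell of 22 by edgeR; 0 and 8 at an unadjusted p under 0.05, 0 and 3 by DESeq2, 0 and 0 by limma, and 0 and 0 adjusted over the list alone; mean log2 fold change -0.73, camera adjusted p = 0.00722, and adjusted p = 0.777 with an estimated correlation), gluconeogenesis and fatty acid oxidation (0 rose and 2 fell of 21, 0 and 4 adjusted over the list alone; mean log2 fold change -0.58, camera adjusted p = 0.00114, and adjusted p = 0.625 with an estimated correlation) and cell wall genes (1 rose and 6 fell of 24, 1 and 8 adjusted over the list alone; mean log2 fold change -0.45, camera adjusted p = 0.00152, and adjusted p = 0.661 with an estimated correlation). TIR1 fell by 1.87 ± 0.32 (adjusted p = 0.00819) and YAT1, carnitine acetyltransferase, fell by 2.29 ± 0.39 (adjusted p = 0.00967).

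Weakest among the lists called were heat shock proteins (1 rose and 3 fell of 25, 1 and 4 adjusted over the list alone; mean log2 fold change -0.53, camera adjusted p = 0.0241, and adjusted p = 0.811 with an estimated correlation) and amino acid biosynthesis (0 rose and 4 fell of 36, 0 and 5 adjusted over the list alone; mean log2 fold change -0.23, camera adjusted p = 0.0376, and adjusted p = 0.827 with an estimated correlation). The heat shock call was lost without hos2 replicate 1 (-0.18, adjusted p = 0.242) and without naive replicate 2 (-0.30, adjusted p = 0.173), and the amino acid call without hos2 replicate 1 (-0.20, adjusted p = 0.0820) and without naive replicate 2 (0.034, adjusted p = 0.926). HSP26 fell by 2.60 ± 0.43 (adjusted p = 0.00778) and SSA4 fell by 2.28 ± 0.32 (adjusted p = 0.00302). The other 16 of 31 lists had adjusted p-values from 0.106 to 0.819. With an estimated correlation 0 lists passed (lowest adjusted p = 0.122, 4 with an unadjusted p under 0.05), and 7 passed by fry. Of 70 named calls 17 held in each fit that left out 1 library, among them HXT4, HXT6, HXT7, BNA2, YKR075C, GPH1, GLC3, SIT1, UTP20 and IMD2. Those of NOP7, UTP22, LSC2, MAL31, TIR1, YAT1 and HSP26 held in 2 of the 4, of FRE1, snR44, YGR160W and HLR1 in 1 and of PCL1 in 0. Leaving out hos2 replicate 1 ended 52, naive replicate 2 43, hos2 replicate 2 25 and naive replicate 1 17.

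The set3 deletion was compared with naive diploids for the transcripts that depend on the complex's histone-binding subunit. As in the hos2 deletion, the hexose transporter and general stress lists were lower and the ribosome biogenesis list higher at the preset correlation. None passed with an estimated one (adjusted p = 0.122 to 0.463). IMD2 fell by 2.31 ± 0.21 (adjusted p = 0.000484; chromosome VIII, 554396 to 555967), BNA5, kynureninase, fell by 2.55 ± 0.26 (adjusted p = 0.000898) and YKR075C fell by 2.82 ± 0.30 (adjusted p = 0.00132). HXT6 fell by 3.66 ± 0.48 (adjusted p = 0.00742), BNA2 fell by 3.44 ± 0.45 (adjusted p = 0.00278) and CYC7, the hypoxic cytochrome c, fell by 2.69 ± 0.43 (adjusted p = 0.0109). Also low were YFR052C-A (-2.76 ± 0.31, adjusted p = 0.00136), HXT4 (-2.67 ± 0.32, adjusted p = 0.00148) and TMA10 (-2.55 ± 0.47, adjusted p = 0.0266). Highest were FRE1 (2.71 ± 0.49, adjusted p = 0.0266), PCL1 (2.01 ± 0.36, adjusted p = 0.0180), HLR1 (1.88 ± 0.34, adjusted p = 0.0179), NOP7 (1.49 ± 0.22, adjusted p = 0.00742), NOP56, of box C/D ribonucleoproteins (1.36 ± 0.26, adjusted p = 0.0221), and REA1, a ribosome assembly ATPase (1.32 ± 0.26, adjusted p = 0.0260). Of 6390 genes tested, 160 passed, 37 higher and 123 lower. The count fell in every fit that left out 1 library, most without set3 replicate 1 and least without naive replicate 1. Such fits also lose replication. With spike-in library sizes, which put the median of all genes at -0.50, 3 genes passed.

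Of the 34 ribosome biogenesis genes tested, 8 rose and 0 fell (27 and 0 adjusted over the list alone). For ribosome biogenesis the mean log2 fold change was 0.75, camera adjusted p = 4.70e-20, and adjusted p = 0.207 with an estimated correlation. Of the 15 hexose transporter genes tested, 0 rose and 4 fell (0 and 9 adjusted over the list alone). For hexose transporters the mean log2 fold change was -1.32, camera adjusted p = 8.56e-11, and adjusted p = 0.122 with an estimated correlation. HXT7 fell by 2.55 ± 0.34 (adjusted p = 0.00348) and HXT1, the low-affinity transporter, fell by 1.59 ± 0.26 (adjusted p = 0.0109). Of the 31 general stress genes tested, 0 rose and 6 fell (0 and 17 adjusted over the list alone). For general stress the mean log2 fold change was -0.97, camera adjusted p = 6.35e-14, and adjusted p = 0.463 with an estimated correlation. GDB1, the glycogen debranching enzyme, fell by 1.57 ± 0.21 (adjusted p = 0.00407) and GPH1 fell by 2.01 ± 0.29 (adjusted p = 0.00602). Of the 41 TCA cycle and respiratory chain genes tested, 0 rose and 4 fell (0 and 5 adjusted over the list alone). For this list the mean log2 fold change was -0.48, camera adjusted p = 8.38e-07, and adjusted p = 0.527 with an estimated correlation. Of the 194 subtelomeric genes tested, 1 rose and 8 fell (1 and 15 adjusted over the list alone). For subtelomeric genes the mean log2 fold change was -0.63, camera adjusted p = 7.33e-07, and adjusted p = 0.527 with an estimated correlation, and the mean was -0.36 (adjusted p = 0.0218) without members that share reads. The list's median was -0.49, or -0.47 with genes at 0 counts set to their bound. Its mean ran from -1.18 to -0.33 in fits without 1 library. PHO11, an acid phosphatase 4.76 kb from an end of chromosome I that shares reads with PHO12, fell by 1.67 ± 0.25 (adjusted p = 0.00742).

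Other lists called lower in the set3 deletion had few or no members past the gene test. They were phosphate genes (0 rose and 1 fell of 17, 0 and 8 adjusted over the list alone; mean log2 fold change -0.64, camera adjusted p = 0.000124, and adjusted p = 0.329 with an estimated correlation), the DAN and TIR mannoproteins (0 rose and 2 fell of 8, 0 and 2 adjusted over the list alone; mean log2 fold change -0.94, camera adjusted p = 0.000362, and adjusted p = 0.310 with an estimated correlation) and maltose genes (0 rose and 2 fell of 13, 0 and 4 adjusted over the list alone; mean log2 fold change -0.75, camera adjusted p = 0.000787, and adjusted p = 0.463 with an estimated correlation). Next came the COS family (0 rose and 0 fell of 11 by edgeR; 0 and 4 at an unadjusted p under 0.05, 0 and 1 by DESeq2, 0 and 0 by limma, and 0 and 1 adjusted over the list alone; mean log2 fold change -0.54, camera adjusted p = 0.0120, and adjusted p = 0.705 with an estimated correlation), thiamine genes (0 rose and 0 fell of 22 by edgeR; 0 and 7 at an unadjusted p under 0.05, 0 and 3 by DESeq2, 0 and 0 by limma, and 0 and 1 adjusted over the list alone; mean log2 fold change -1.03, camera adjusted p = 0.000762, and adjusted p = 0.661 with an estimated correlation) and galactose genes (0 rose and 1 fell of 9, 0 and 1 adjusted over the list alone; mean log2 fold change -0.60, camera adjusted p = 0.0204, and adjusted p = 0.527 with an estimated correlation). Last were gluconeogenesis and fatty acid oxidation (0 rose and 1 fell of 21, 0 and 1 adjusted over the list alone; mean log2 fold change -0.48, camera adjusted p = 0.00294, and adjusted p = 0.661 with an estimated correlation), glycolysis and fermentation (0 rose and 0 fell of 18 by edgeR; 0 and 5 at an unadjusted p under 0.05, 0 and 3 by DESeq2, 0 and 0 by limma, and 0 and 3 adjusted over the list alone; mean log2 fold change -0.62, camera adjusted p = 0.000347, and adjusted p = 0.759 with an estimated correlation), cell wall genes (0 rose and 2 fell of 24, 0 and 3 adjusted over the list alone; mean log2 fold change -0.35, camera adjusted p = 0.00640, and adjusted p = 0.687 with an estimated correlation) and the telomeric Y' element helicases (0 rose and 0 fell of 8 by edgeR; 0 and 1 at an unadjusted p under 0.05, 0 and 1 by DESeq2, 0 and 0 by limma, and 0 and 1 adjusted over the list alone; mean log2 fold change -0.76, camera adjusted p = 0.0226, and adjusted p = 0.759 with an estimated correlation). Without naive replicate 2 the calls of glycolysis (-0.26, adjusted p = 0.251), cell wall genes (-0.20, adjusted p = 0.173) and Y' helicases (-0.52, adjusted p = 0.124) were lost, the last also without set3 replicate 1 (-0.52, adjusted p = 0.177).

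Ribosomal protein genes as a list were slightly higher in the set3 deletion. Of the 137 ribosomal protein genes tested, 0 rose and 0 fell by edgeR (4 and 0 at an unadjusted p under 0.05, 1 and 0 by DESeq2, 0 and 0 by limma, and 0 and 0 adjusted over the list alone). For ribosomal proteins the mean log2 fold change was 0.18, camera adjusted p = 0.00533, and adjusted p = 0.827 with an estimated correlation, and with spike-in library sizes the list lay 0.25 above the median of all genes. The call was lost without naive replicate 1 (0.10, adjusted p = 0.406) and without set3 replicate 1 (-0.076, adjusted p = 0.602). The other 15 of 31 lists had adjusted p-values from 0.0932 to 0.855. With an estimated correlation 0 passed (lowest adjusted p = 0.122, 4 with an unadjusted p under 0.05), and 5 passed by fry. Of 51 named calls only those of IMD2, YKR075C, BNA5 and SET3 held in each fit that left out 1 library. Those of FRE1, PCL1, HLR1, NOP56 and REA1 held in 0 of the 4. Leaving out set3 replicate 1 ended 46, set3 replicate 2 45, naive replicate 2 31 and naive replicate 1 28.

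The snt1 deletion was compared with naive diploids for the transcripts that depend on the SANT-domain subunit. Most calls were lower, and some iron uptake transcripts were higher. SIT1 rose by 2.55 ± 0.29, adjusted p = 0.00191 (chromosome V, 27657 to 29543), FET3, the ferroxidase of high-affinity iron uptake, by 2.43 ± 0.26, adjusted p = 0.00118 (chromosome XIII, 388822 to 390732), and its partner permease FTR1 by 1.89 ± 0.28, adjusted p = 0.0105. The only other gene called higher was YGR137W, a dubious reading frame with shared reads (1.21 ± 0.21, adjusted p = 0.0251). Lowest was YJL026C-A, with 0 counts and at least 133-fold lower, a target that shares reads. YKR075C fell by 3.50 ± 0.32 (adjusted p = 0.000316), IMD2 fell by 2.52 ± 0.21 (adjusted p = 0.000199) and HXT1 fell by 2.22 ± 0.27 (adjusted p = 0.00262). BNA2 fell by 2.72 ± 0.43 (adjusted p = 0.0141), YJR115W fell by 1.98 ± 0.25 (adjusted p = 0.00337) and BNA4, kynurenine monooxygenase, fell by 1.76 ± 0.23 (adjusted p = 0.00406). MIG3, a transcriptional repressor, had -1.85 ± 0.28, adjusted p = 0.0134, TIR1 -1.78 ± 0.32, adjusted p = 0.0374, YER067C-A, a reading frame that overlaps RGI1, -1.87 ± 0.28, adjusted p = 0.0113, and YRF1-3 and YRF1-7, which cannot be told apart, -2.88 ± 0.46, adjusted p = 0.0256. Of 6390 genes tested, 29 passed, 4 higher and 25 lower. The count rested on single libraries, as 19 (2 and 17) and 18 (5 and 13) genes (higher and lower) passed without naive replicate 1 and 2. It was 320 (183 and 137) and 55 (13 and 42) without snt1 replicate 1 and 2. With spike-in library sizes, which put the median of all genes at -0.66, 3 genes passed.

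Of the 21 iron regulon genes tested, 3 rose and 0 fell (7 and 0 adjusted over the list alone). For the iron regulon the mean log2 fold change was 0.71, camera adjusted p = 5.85e-12, and adjusted p = 0.122 with an estimated correlation. Of the 15 hexose transporter genes tested, 0 rose and 1 fell (0 and 5 adjusted over the list alone). For hexose transporters the mean log2 fold change was -0.99, camera adjusted p = 2.48e-09, and adjusted p = 0.122 with an estimated correlation. Of the 194 subtelomeric genes tested, 0 rose and 5 fell (3 and 11 adjusted over the list alone). For subtelomeric genes the mean log2 fold change was -0.40, camera adjusted p = 4.45e-05, and adjusted p = 0.620 with an estimated correlation, and without members that share reads the mean was -0.28 and did not pass (adjusted p = 0.204). YHR214C-B, a Ty element reading frame with shared reads, fell by 1.59 ± 0.25 (adjusted p = 0.0135). Called higher as lists without a member past the gene test were ribosomal proteins (0 rose and 0 fell of 137 by edgeR; 12 and 0 at an unadjusted p under 0.05, 0 and 0 by DESeq2, 0 and 0 by limma, and 0 and 0 adjusted over the list alone; mean log2 fold change 0.30, camera adjusted p = 4.30e-09, and adjusted p = 0.759 with an estimated correlation) and ribosome biogenesis (0 rose and 0 fell of 34 by edgeR; 10 and 0 at an unadjusted p under 0.05, 2 and 0 by DESeq2, 0 and 0 by limma, and 0 and 0 adjusted over the list alone; mean log2 fold change 0.38, camera adjusted p = 4.03e-08, and adjusted p = 0.463 with an estimated correlation). With spike-in library sizes they lay 0.38 and 0.43 above the median of all genes. Lower were general stress (0 rose and 0 fell of 31 by edgeR; 0 and 8 at an unadjusted p under 0.05, 0 and 0 by DESeq2, 0 and 0 by limma, and 0 and 4 adjusted over the list alone; mean log2 fold change -0.29, camera adjusted p = 0.00294, and adjusted p = 0.811 with an estimated correlation), the DAN and TIR mannoproteins (0 rose and 1 fell of 8, 0 and 2 adjusted over the list alone; mean log2 fold change -0.93, camera adjusted p = 0.000762, and adjusted p = 0.329 with an estimated correlation) and maltose genes (0 rose and 0 fell of 13 by edgeR; 0 and 5 at an unadjusted p under 0.05, 0 and 0 by DESeq2, 0 and 0 by limma, and 0 and 3 adjusted over the list alone; mean log2 fold change -0.49, camera adjusted p = 0.00412, and adjusted p = 0.527 with an estimated correlation). So were haploid-specific genes (0 rose and 0 fell of 24 by edgeR; 1 and 3 at an unadjusted p under 0.05, 0 and 1 by DESeq2, 0 and 0 by limma, and 0 and 1 adjusted over the list alone; mean log2 fold change -0.55, camera adjusted p = 0.0231, and adjusted p = 0.811 with an estimated correlation), thiamine genes (0 rose and 0 fell of 22 by edgeR; 0 and 3 at an unadjusted p under 0.05, 0 and 0 by DESeq2, 0 and 0 by limma, and 0 and 0 adjusted over the list alone; mean log2 fold change -0.49, camera adjusted p = 0.0241, and adjusted p = 0.811 with an estimated correlation) and the Y' element helicases (0 rose and 2 fell of 8, 1 and 2 adjusted over the list alone; mean log2 fold change -0.16, camera adjusted p = 0.0368, and adjusted p = 0.789 with an estimated correlation). Set3 complex subunits were called lower (mean log2 fold change -0.98, camera adjusted p = 0.0108, and adjusted p = 0.591 with an estimated correlation), a list that holds the deleted SNT1 and whose median was -0.020 (0.015 with DESeq2's size factors). A replicate block ended that call (-0.99, adjusted p = 0.0762).

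Several of these snt1 calls were lost without 1 library, some at means that moved little. Without snt1 replicate 1 this held for general stress (-0.17, adjusted p = 0.513), the mannoproteins (-0.64, adjusted p = 0.111), the Set3 complex subunits (-0.79, adjusted p = 0.291), thiamine genes (-0.50, adjusted p = 0.258), haploid-specific genes (-0.68, adjusted p = 0.129) and the Y' helicases, whose mean turned (0.30, adjusted p = 0.487). Without naive replicate 2 it held for maltose genes (-0.47, adjusted p = 0.0581), thiamine genes (-0.36, adjusted p = 0.359) and the Y' helicases, whose mean also turned (0.068, adjusted p = 0.446). The haploid-specific call was also lost without naive replicate 1 (-0.18, adjusted p = 0.276) and without snt1 replicate 2 (-0.56, adjusted p = 0.0978). It was lost too with background subtraction (-0.42, adjusted p = 0.0955) and with both corrections (-0.38, adjusted p = 0.0706). The other 19 of 31 lists had adjusted p-values from 0.0757 to 0.905. With an estimated correlation 0 passed (lowest adjusted p = 0.122, 3 with an unadjusted p under 0.05), and 3 passed by fry. Of 22 named calls 9 held in each fit that left out 1 library, namely SIT1, FET3, YKR075C, IMD2, HXT1, YJR115W, BNA4, YJL026C-A and SNT1. Those of TIR1, YRF1-3 and YRF1-7 held in 1 of the 4. The PAU family, AAD dehydrogenases, flocculins, sulfur amino acid genes, ergosterol genes and the multidrug and oxidative stress list passed in none of the 4 comparisons with naive under the main settings. All of these but the AAD list passed under some other setting. Fits without 1 library filter genes anew, so the members behind their means can differ from those of the main fit. PAU genes passed in [ESI+] without [ESI+] replicate 1 (2.11, adjusted p = 0.0200). They also passed in hos2 without hos2 replicate 2 (-0.95, adjusted p = 0.0400), and sulfur amino acid genes in snt1 without snt1 replicate 1 (0.45, adjusted p = 0.000750). Ergosterol genes passed without naive replicate 1 in [ESI+] (-0.45, adjusted p = 0.0116), hos2 (-0.37, adjusted p = 0.00971) and set3 (-0.35, adjusted p = 0.00622). They also passed in [ESI+] without [ESI+] replicate 1 (-0.37, adjusted p = 0.0283) and in snt1 without naive replicate 2 (0.24, adjusted p = 0.0214). The multidrug list passed without naive replicate 2 in set3 (0.24, adjusted p = 0.0264) and snt1 (0.34, adjusted p = 0.00852), and in snt1 without snt1 replicate 1 (0.38, adjusted p = 0.00237). Flocculins passed with the length trend removed in [ESI+] (-0.80, adjusted p = 0.0119) and hos2 (-0.56, adjusted p = 0.0428). With both corrections they passed in [ESI+] (-1.13, adjusted p = 0.000191), hos2 (-0.57, adjusted p = 0.0369) and set3 (-0.52, adjusted p = 0.0483). Among lists that were not called, median, mean and test differed in sign for PAU genes, Y' helicases, thiamine genes, hexose transporters, gluconeogenesis, sulfur amino acid genes and multidrug transporters in [ESI+]. They did so for early meiotic genes and multidrug transporters in the hos2 deletion, Set3 complex subunits and the iron regulon in the set3 deletion, and flocculins and phosphate genes in the snt1 deletion.

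**Figure D3:**
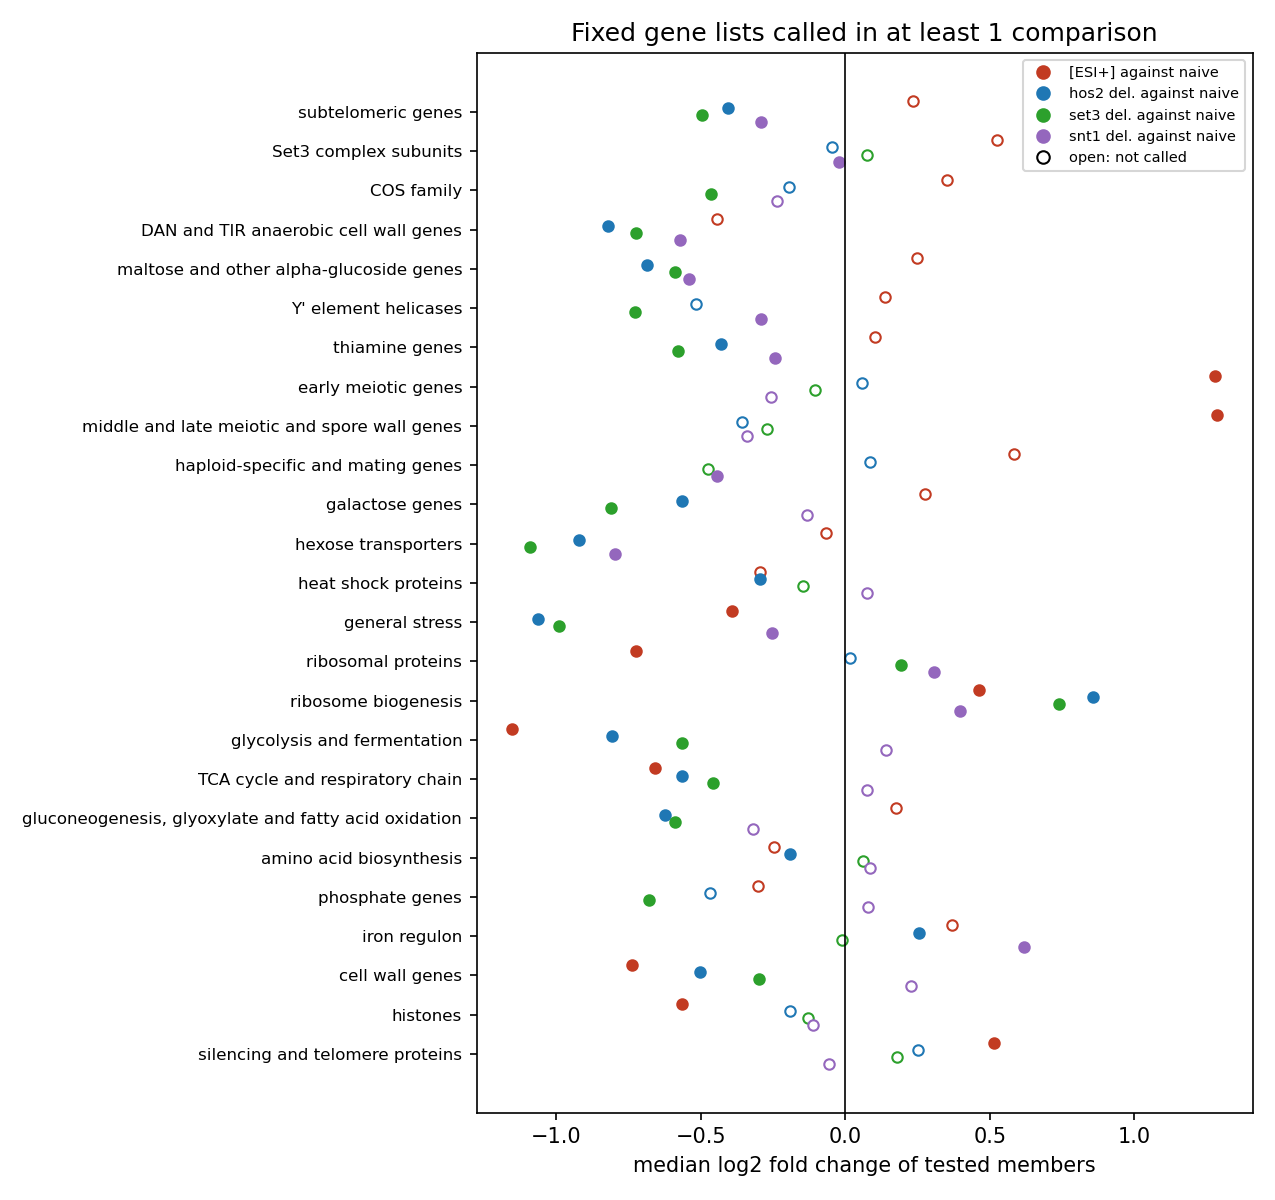
Median log2 fold change against naive (x axis) of the tested members of each fixed list called in at least 1 comparison (y axis), with filled points for lists past the camera threshold at the preset correlation and open points for the others. Ribosome biogenesis was called higher in all 4 comparisons, at medians of 0.46 in [ESI+] and 0.86, 0.74 and 0.40 in the hos2, set3 and snt1 deletions. All 4 calls were lost with an estimated correlation (adjusted p = 0.661, 0.207, 0.207 and 0.463 in that order).

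By edgeR 16 genes passed downward in all 3 deletions and 0 upward. Counts were 160 and 93 at an unadjusted p under 0.05, 37 and 14 by DESeq2 and 6 and 0 by limma. In the order hos2, set3, snt1, IMD2 had log2 fold changes of -2.33 ± 0.21, -2.31 ± 0.21 and -2.52 ± 0.21 (largest adjusted p = 0.000484), YKR075C -3.46 ± 0.31, -2.82 ± 0.30 and -3.50 ± 0.32 (largest adjusted p = 0.00132) and BNA4 -1.69 ± 0.22, -1.93 ± 0.23 and -1.76 ± 0.23 (largest adjusted p = 0.00406). MTH1, a repressor of hexose transporter genes, had -2.50 ± 0.21, -1.79 ± 0.21 and -1.52 ± 0.21 (largest adjusted p = 0.00620) and BNA2 -3.62 ± 0.43, -3.44 ± 0.45 and -2.72 ± 0.43 (largest adjusted p = 0.0141). YJR115W, RGI1 and NRT1, a nicotinamide riboside transporter, had largest adjusted p-values of 0.0104, 0.0241 and 0.0241. Of the 4 fits without 1 library, the set3 calls of BNA4, MTH1 and BNA2 held in 2, of YJR115W in 1 and of RGI1 in 0. Joint calls rest on the same naive libraries and are not independent. Of the 16 genes, 7 were also called lower in [ESI+] and 9 were not called. There, called were IMD2 (-1.02 ± 0.20, adjusted p = 0.00530), BNA4 (-0.78 ± 0.22, adjusted p = 0.0214), BNA2 (-2.18 ± 0.40, adjusted p = 0.00320), YJR115W (-1.52 ± 0.24, adjusted p = 0.00173) and NRT1 (-0.88 ± 0.21, adjusted p = 0.0111). Not called were YKR075C (-0.76 ± 0.27, adjusted p = 0.0566), MTH1 (-0.30 ± 0.20, adjusted p = 0.274) and RGI1 (-0.14 ± 0.27, adjusted p = 0.727).

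**Figure D4:**
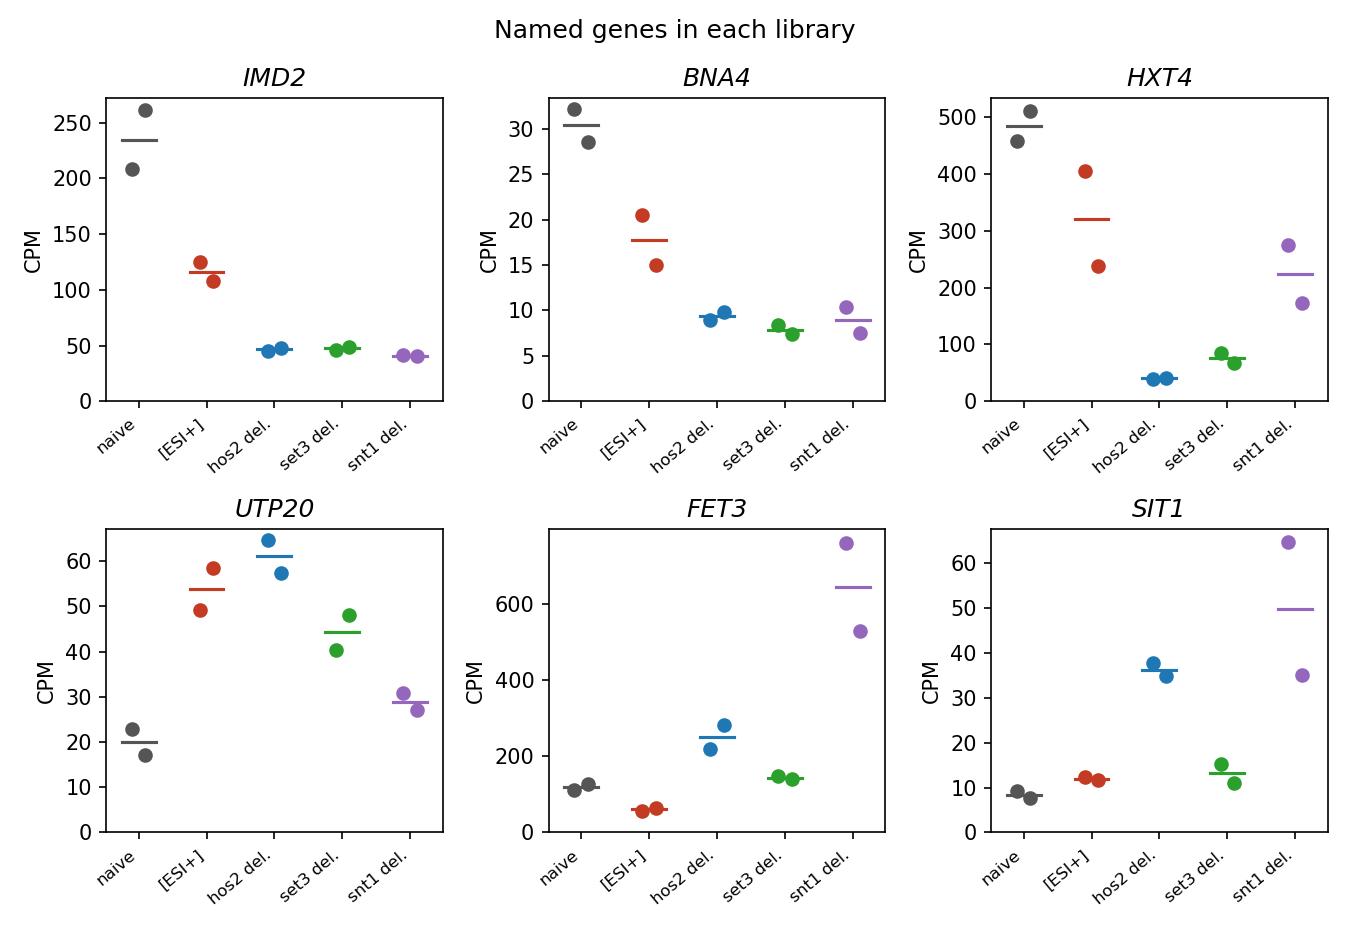
CPM (y axis, linear from 0) of IMD2, BNA4, HXT4, UTP20, FET3 and SIT1 in each library by group, with a line at each group's mean. IMD2 and BNA4 lay lower in every deletion library than in both naive libraries.

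Direct tests asked whether [ESI+] differs from each deletion without the naive libraries in the contrast. 481 genes differed between [ESI+] and the hos2 deletion (245 higher and 236 lower in [ESI+]), 1032 from the set3 deletion (525 and 507) and 2363 from the snt1 deletion (1192 and 1171). MTH1 was higher in [ESI+] than in the hos2 deletion (2.20 ± 0.21, adjusted p = 0.000760) and the set3 deletion (1.49 ± 0.21, adjusted p = 0.00315). HXT4 was 2.997 ± 0.32, adjusted p = 0.000838 over the hos2 deletion and HXT1 2.25 ± 0.27, adjusted p = 0.000443 over the snt1 deletion. YLR154W-E, a reading frame in the ribosomal DNA with shared reads, was higher in [ESI+] than in the hos2, set3 and snt1 deletions (2.44 ± 0.26, 2.65 ± 0.26 and 2.47 ± 0.26; largest adjusted p = 0.000838). SMX3, a core splicing protein, was lower in [ESI+] in all 3 tests (-1.91 ± 0.21, -2.25 ± 0.22 and -2.88 ± 0.22; largest adjusted p = 0.000838). FET3 was lower in [ESI+] than in the hos2 deletion (-2.04 ± 0.26, adjusted p = 0.00174) and the snt1 deletion (-3.41 ± 0.27, adjusted p = 4.52e-05). YPL257W-B was at least 285-fold and 232-fold higher than in the hos2 and set3 deletions, and YJL026C-A at least 297-fold and 292-fold lower, both with shared reads. Splits into higher and lower, in parentheses, were less even in several fits that left out 1 library. Counts were 40 (34 and 6), 50 (30 and 20) and 716 (334 and 382) without [ESI+] replicate 2. They were 248 (183 and 65), 399 (257 and 142) and 1567 (859 and 708) without [ESI+] replicate 1. Without hos2 replicates 1 and 2 the first count was 90 (29 and 61) and 48 (26 and 22). Without set3 replicates 1 and 2 the second was 75 (15 and 60) and 305 (112 and 193). Without snt1 replicates 1 and 2 the third was 2774 (1289 and 1485) and 1884 (806 and 1078). Spike-in library sizes left 34, 48 and 64.

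Among the deletions themselves, 60 genes differed by a test over all 3 (edgeR F-test), with 2 between set3 and hos2, 12 between snt1 and set3 and 202 between snt1 and hos2. The 2 between set3 and hos2 were named after their values were seen and are the deleted genes themselves, SET3 and HOS2. In the test over all 3 the deleted genes SNT1, SET3 and HOS2 had the lowest adjusted p-values (4.05e-05, 4.51e-05 and 4.51e-05). COQ21 came next (adjusted p = 0.000506), with log2 fold changes against naive of -2.32 ± 0.23, -1.82 ± 0.23 and 0.080 ± 0.22 in the hos2, set3 and snt1 deletions. HXT7 had -3.85 ± 0.36, -2.55 ± 0.34 and -0.82 ± 0.32 (adjusted p = 0.00433) and FET3 1.06 ± 0.25, 0.26 ± 0.25 and 2.43 ± 0.26 (adjusted p = 0.00433). ALD4, mitochondrial aldehyde dehydrogenase, had -1.51 ± 0.25, -1.15 ± 0.25 and 0.46 ± 0.24 and HOR7 -1.69 ± 0.25, -1.33 ± 0.25 and 0.28 ± 0.25 (adjusted p = 0.00433 for each, and for YNL284C-B, a Ty reading frame with shared reads). The count was 12 and 14 without hos2 replicates 1 and 2, 17 and 14 without set3 replicates 1 and 2, and 755 and 113 without snt1 replicates 1 and 2.

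Whether [ESI+] and loss of the complex move the same transcripts was read from the fold changes against the shared naive libraries, across 6390 genes, which are not independent replicates. The [ESI+] and hos2 fold changes correlated at Pearson r = 0.534 (0.527 on average in simulated unchanged groups), with a covariance of 0.481 against 0.121. The [ESI+] and set3 fold changes correlated at Pearson r = 0.4005 (simulated 0.517), with a covariance of 0.346 against 0.120. Those of [ESI+] and snt1 correlated at Pearson r = 0.0856 (simulated 0.518), with a covariance of 0.0644 against 0.122. Between deletions the covariance was 0.460 for hos2 and set3 (simulated 0.122), 0.199 for hos2 and snt1 (simulated 0.122) and 0.2001 for set3 and snt1 (simulated 0.121). Genes called in the same direction numbered 305 for [ESI+] and hos2 (121 higher and 184 lower). Independent lists of those sizes would share 26.2 and 43.4. Simulated unchanged groups shared 0.0900 on average, but have too few calls to show what shared controls add. For [ESI+] and set3 they numbered 91 (25 and 66, against 5.13 and 17.8), and for [ESI+] and snt1 9 (1 and 8, against 0.555 and 3.62). Genes called in opposite directions numbered 3, 1 and 3 in these pairs. The naive group was not split, as that leaves 1 library on each side. Shared controls may give part of the excess over independent lists.

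These values moved in fits without 1 library, which also lose replication. For [ESI+] and hos2 r was 0.254 and the overlap 12 without hos2 replicate 1. The overlap was 95 without hos2 replicate 2, 23 without naive replicate 2, and 116 and 61 without [ESI+] replicates 1 and 2. For [ESI+] and set3 r was 0.104 without set3 replicate 1 and 0.649 without naive replicate 1. Its overlap ran from 5 without set3 replicate 1 to 51 without [ESI+] replicate 1, below the full value in every such fit, with 6 without set3 replicate 2, 18 without [ESI+] replicate 2, and 33 and 11 without naive replicates 1 and 2. For [ESI+] and snt1 r was -0.0136 without snt1 replicate 1, 0.479 without naive replicate 1 and 0.197 without naive replicate 2. The overlap was 73 without snt1 replicate 1 and 4 without [ESI+] replicate 2.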

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

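Of the tests here, those of silent-gene position, of spike-in length and of matched lists were set down before their results were seen; the tests of length across silent genes, of targets away from chromosome ends, of the background and length corrections, of spike-in slopes and of shared reads were chosen only after the result was seen.

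A test of the difference itself singled out the genes that differed between [ESI+] and the hos2 (481), set3 (1032) and snt1 (2363) deletions, and among the deletions (60, the deleted genes included). Against the hos2 deletion the named log2 fold changes in [ESI+] were 2.20 for MTH1, 2.44 for YLR154W-E, 2.997 for HXT4, 2.70 for YKR075C, -1.91 for SMX3, -2.04 for FET3, -2.18 for RPL43A and -2.05 for YNL057W. Against the set3 deletion they were 2.65 for YLR154W-E, 1.58 for YPS6, 1.49 for MTH1, 3.23 for MOR1, -2.25 for SMX3, -1.64 for MIM2, -3.12 for YHR165W-A and -1.72 for YDL012C. Against the snt1 deletion they were 2.51 for YNL284C-B, 2.47 for YLR154W-E, 2.24 for YHR214C-B, 2.74 for YKR075C, 2.25 for HXT1, -2.88 for SMX3, -3.00 for COQ21, -3.41 for FET3, -2.33 for YJL152W and -2.91 for MIC10. YPL257W-B was at least 285-fold higher in [ESI+] than in hos2 and 232-fold higher than in set3, and YJL026C-A at least 297-fold and 292-fold lower. Among the deletions the adjusted p was 0.000506 for COQ21, 0.00433 for each of HXT7, FET3, ALD4, YNL284C-B and HOR7, 0.00586 for HXT4, 0.00617 for FTR1, 0.00799 for INH1 and 0.0109 for YJL152W. Spike-ins took 0.946% and 5.19% of the [ESI+] libraries. URA3, an auxotrophic marker, had 3.89 and 25.6 CPM in [ESI+] replicates 1 and 2, and at most 0.597 CPM elsewhere; the labels do not say whether the [ESI+] strain carries a URA3 marker, so this is not read as a change in expression.

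The [ESI+] libraries had reads at genes silent elsewhere and at mitochondrial targets, and 886 genes were called higher in them than in naive cells. Across silent genes, which are not independent replicates, pooled [ESI+] counts followed coding length (Spearman 0.809). Counts from RNA could too, so the test cannot tell DNA from RNA. Transcription of silenced genes near chromosome ends cannot account for the pattern as a whole, since silent genes farther in had medians of 0.347 and 1.56 CPM per kb in [ESI+] replicates 1 and 2 (95% intervals 0.280 to 0.423 and 1.497 to 1.62, at most 0.111 elsewhere) and mitochondrial targets 3.50 and 13.4 (2.26 to 5.66 and 10.5 to 18.8, at most 0.239 elsewhere). For the 8 silent genes near ends it stays open: the median per kb near ends over that farther in was 1.01 (95% interval 0 to 1.41) in replicate 1 and 0.949 (0.416 to 1.09) in replicate 2. Genomic DNA cannot account for all upward calls, since 72.3% of them passed in the same direction after background subtraction, while both meiotic lists did not, and another group-wide difference in the [ESI+] cells was not tested.

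Fold changes in [ESI+] against naive rose with coding length (Spearman 0.279 across tested genes). This trend is not the whole source of the calls, since 60.1% passed in the same direction once each library's trend was removed, 46.2% of upward and 73.4% of downward ones. A length bias of library preparation stays open, as the spike-ins gave 0.0471 with an interval from -0.284 to 0.390 over 42 of them, 505 to 1994 bases long. A compressed range of amounts stays open too, with spike-in slopes of 0.994 ± 0.0610 (SE) and 1.01 ± 0.0331 in [ESI+] replicates 1 and 2 beside gene slopes of 0.910 and 0.835. A change in the cells that follows length, as ribosomal protein genes are short and ribosome assembly genes long, could give the same trend and was not tested.

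Subtelomeric genes were lower as a list in each deletion at camera's preset correlation, but not with an estimated one (adjusted p = 0.661, 0.527 and 0.620 in hos2, set3 and snt1). Low expression and short length cannot account for it: 0% of 10000 random lists matched on both lay below the list's median in hos2, 0% in set3 and 0% in snt1, with medians of -0.41 against 0.036, -0.49 against -0.062 and -0.29 against -0.10 in the matched lists. Shared reads cannot account for all of it in set3, where the mean without such genes was -0.356 and passed (adjusted p = 0.0218). In hos2 (-0.255, adjusted p = 0.142) and snt1 (-0.283, adjusted p = 0.204) shared reads stay open, as the means kept their sign without passing. A role of the complex at chromosome ends was not tested.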

How the results depend on the processing

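The fits with reads at silent genes subtracted, with the length trend removed, with both, and with nuclear protein-coding genes alone were chosen only after the result was seen. Under the settings fixed beforehand, values for whole comparisons kept direction, side of the threshold and a count within 1.5 times in 138 instances and a count or correlation moved further in 101. Another 5 lost the threshold, 2 gained it and 2 reversed. Under the 4 later ones 55 were kept, 7 moved and 2 reversed. Where values were not kept, the cause was not tested, except where fewer genes were tested (a CPM filter, no shared reads, protein-coding genes) or a fold over 2 was asked. Of 255 named calls, 253 kept direction and threshold with DESeq2, 250 with RLE size factors, 252 with the block, 169 with limma-trend, 225 with the length trend removed and 26 with spike-in library sizes, where 228 lost the threshold. The gene reversed among these settings was HTB1 in [ESI+], with 0.076 under spike-in and 0.17 under limma-trend. Spike-in medians of all genes, given above, rest on naive spike-in shares of 1.43% and 3.31%. Without 1 library, the lone sample of its group was assumed to vary like the other groups. Depth was lowest in set3 replicate 2.

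Spike-in library sizes left 32 genes in [ESI+], 5 in hos2, 3 in set3 (2 higher, 1 lower) and 3 in snt1 (0 and 3). Against hos2, set3 and snt1, [ESI+] had 34 (25 higher and 9 lower), 48 (38 and 10) and 64 (52 and 12). Among deletions 8 passed. With limma-trend (median of all genes 0.74 in [ESI+]) counts were 2851 (2659 higher and 192 lower), 121 (61 and 60), 35 and 18. Then came 264 (233 and 31) and 4267 (4078 and 189) against hos2 and snt1, and 20 among deletions. Against set3 the split was 1447 and 67. With DESeq2, 747 passed in hos2, 399 in set3 (146 higher and 253 lower), 99 in snt1 (41 higher and 58 lower), 874 in [ESI+] against hos2 and 515 among deletions. It gave no adjusted p for 124 genes in hos2 and 372 in set3. With only the groups compared, 555 passed in set3 (201 higher and 354 lower), 6 in snt1 (0 higher and 6 lower), 2018, 2352 and 1375 against hos2, set3 and snt1, and 16 among deletions.

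With a replicate block, 848 genes passed in hos2, 403 in set3 (146 higher and 257 lower), 59 in snt1, 977 and 1660 in [ESI+] against hos2 and set3, and 348 among deletions, with overlaps of 584, 245 and 17 genes for [ESI+] and hos2, set3 and snt1. Deviations of equal replicate numbers correlated at only -0.0728 to 0.346 between groups, so the numbers were not taken to pair libraries. The block ended the call of Set3 complex subunits in snt1 (adjusted p = 0.0762). At a mean of at least 10 CPM, 153 genes differed among deletions and r was 0.719 for [ESI+] and hos2 and 0.623 for [ESI+] and set3. Without genes of shared reads, 19 passed in snt1 and 119 among deletions, and the subtelomeric means were -0.25 in hos2 and -0.28 in snt1, neither past the threshold. With a fold over 2, 1030 passed in [ESI+], 295 in hos2 (68 higher and 227 lower), and 606 and 1468 in [ESI+] against set3 and snt1. With an estimated correlation 0 lists passed in each comparison with naive, and the subtelomeric means of -0.48, -0.63 and -0.40 in hos2, set3 and snt1 no longer did. By fry 4, 7, 5 and 3 lists passed in [ESI+], hos2, set3 and snt1.

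With background subtraction 659 genes passed in [ESI+] against set3, 30 among deletions and 6 lists in [ESI+], whose subtelomeric mean was -0.28. With the length trend removed too, 320, 507 and 33 passed against hos2, set3 and among deletions, with a subtelomeric mean of -0.27 in [ESI+]. With the length trend alone removed the [ESI+] calls split 516 higher and 852 lower. With nuclear protein-coding genes 116 differed among deletions.

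Without 1 library, calls ran from 275 to 1619 in [ESI+], 26 to 355 in hos2, 7 to 54 in set3 and 18 to 320 in snt1. They ran from 40 to 248, 50 to 399 and 716 to 2774 in [ESI+] against hos2, set3 and snt1, and from 12 to 755 among deletions. The subtelomeric mean in [ESI+] ran from -0.12 to 1.09, and it ran from -0.74 to -0.25 in hos2, -1.18 to -0.33 in set3 and -0.86 to -0.29 in snt1, and every such fit of a deletion kept the call at the preset correlation. With an estimated correlation the call was lost with all libraries in (adjusted p = 0.661, 0.527 and 0.620 in hos2, set3 and snt1). Because fits without 1 library filter genes anew, their means need not be over the same members. At the preset correlation the means in this order were -0.25, -0.32 and -0.21 with a distance of 40 kb and -0.52, -0.78 and -0.50 with 10 kb, all past the threshold. For [ESI+] and hos2, set3 and snt1 in turn, r ran from 0.254 to 0.703, 0.104 to 0.649 and -0.0136 to 0.479, and overlaps from 12 to 260, 5 to 51 and 4 to 73 genes.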

Other observations

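Of Set3 complex subunits in [ESI+], HOS2 and SET3 were at 0.95 ± 0.31, adjusted p = 0.0379 and 0.86 ± 0.28, adjusted p = 0.0406. Each call held in only 1 of the 4 fits without 1 library. Both had at most 5.73 CPM in naive, and background (1.55 CPM per kb in [ESI+] replicate 2) may raise them. SNT1 was at 0.58 ± 0.30, adjusted p = 0.162, HOS4 at 0.010 ± 0.17, adjusted p = 0.969 and SIF2 at -0.020 ± 0.18, adjusted p = 0.946. CPR1, the cyclophilin found with the complex, fell by 1.71 ± 0.34 (adjusted p = 0.00513), and HST1, a deacetylase, was at 0.52 ± 0.20, adjusted p = 0.0623. Of the auxotrophic markers, HIS3 fell by 1.98 ± 0.30 in [ESI+] (adjusted p = 0.00144), from 76.3 and 121 CPM in naive replicates 1 and 2 to 26.1 and 23.9 CPM. URA3 was at 5.77 ± 0.97, adjusted p = 0.00417, not read as a change in expression, as above. LEU2 was at 1.75 ± 0.74, adjusted p = 0.0933, LYS2 at 0.30 ± 0.24, adjusted p = 0.371 and MET17 at 0.28 ± 0.26, adjusted p = 0.444. In the deletions the markers' adjusted p-values against naive were 0.218 or more.

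In [ESI+] the subtelomeric list's median was 0.23 against 0.40 in lists matched on expression and length, of which 0.140% lay below it. Background subtraction, which brought the list's mean to -0.28, was chosen only after the result was seen.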
